A study of Mus musculus with 4 samples.

How the data were processed

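The data are 3' mRNA sequencing libraries from 4 mouse liver samples, all on a normal diet and 2 months old. The control group holds 2 samples with loxP-flanked Ubc13 alleles and no albumin-Cre, and the deletion group holds 2 samples with the same alleles and albumin-Cre, a transgene that deletes flanked DNA in hepatocytes. Ubc13 is the protein of the gene Ube2n. The labels number the replicates 1 and 2 in each group and do not say that they came from separate animals, so every p-value measures only the spread between these samples. The deletion replicates were not repeats of the same RNA, because Y-linked genes had 0 counts in replicate 1 and 206 to 719 in replicate 2. Whether the spread between the controls is technical is not known. The labels name liver as the source, while their library protocol speaks of primary hepatocyte RNA; the samples are called liver libraries here, and which material was sequenced was not settled.

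Per the labels' protocols, libraries were made with the QuantSeq 3' kit from oligo-dT primed RNA and read as single-end 75 bp reads on a NextSeq 550. A library of this kind reads 1 short stretch near the 3' end of each transcript, so a count follows the number of transcripts and not their length. Reads were aligned with Bowtie2, and edgeR with TMM and CPM normalization was used for differential expression, per the labels' protocols. The submitters' processing notes name the builds mm10 and GRCm38, which are names of 1 mouse assembly. The counting program, its strand setting, its treatment of reads with several matches and the gene annotation are not given in the sources used here. The authors deposited 1 table of raw counts per gene, with 56953 Ensembl gene rows and 4 columns of whole numbers, and the labels state which column belongs to which sample. The table has 0 other columns and no row without a gene identifier.

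Symbols were taken by identifier from GENCODE release M21 (GRCm38), which matched 52029 of the 56953 rows. The other 4924 rows, which held 0.188% to 0.233% of the counts of a library, kept their identifiers, and they point to an annotation other than M21 in the authors' counting. Where 2 identifiers shared a symbol, which concerned 66 rows, the identifier with more counts kept it. Coordinates are those of M21 on GRCm38, counted from 1. Genes in near-identical families, such as the major urinary proteins (Mup), the Cyp2c, Cyp4a, Ugt2b and Serpina1 genes and the glutathione transferases, can share reads, and their single values are uncertain. Antisense and overlapping genes are uncertain too.

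The deposited counts summed to 17800138 and 16270424 in control replicates 1 and 2 and to 16927947 and 17114003 in deletion replicates 1 and 2. A count of 3 in a library corresponds to between 0.169 and 0.184 CPM, which was taken as the floor. Intervals on shares of counts are exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, because the reads carry no molecular identifiers that were used here. Replicates were compared before they were grouped: over genes with 10 or more counts, a chi-square of the counts per degree of freedom was 41.9 for the controls and 27.9 for the deletion libraries, so neither pair was 1 library deposited under both names.

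Groups were compared with the edgeR 4.0.16 quasi-likelihood F test (two-sided, genotype as the only term) in R 4.3.3. Scaling was by TMM, and genes were kept by filterByExpr at its defaults (a minimum count of 10 and a total of 15), which left 14600. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The fit had 2 residual degrees of freedom and a prior of 4.14. A positive log2 fold change means higher in the deletion libraries, its standard error (SE) was taken as the absolute log2 fold change over the square root of F, and CPM values are scaled by the TMM factors. Values after ± are SE for log2 fold changes and SD over 2 libraries for CPM. With 2 libraries against 2, the smallest two-sided exact permutation p is 0.333, so no single value was tested that way. For genes with 3 or fewer counts over a whole group, the text gives the ratio of scaled counts with an exact counting interval. At 0 counts it gives the ratio against 3 counts over the group and the lower limit of the counting interval.

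A set of 36 gene lists (pathways, cell type markers and sex-linked genes) was written before the data were examined, as were the main tests, most of the alternatives and the rule for named genes. The lists hold 938 tested symbols, of which 54 are in more than 1 list. Lists were tested with camera from limma 3.58.1, which compares a list with all other genes, at a preset correlation of 0.01 between genes, adjusted over the 36 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, stand beside it. With an estimated correlation 0 of the 36 lists passed (6 had an unadjusted p under 0.05, and fry called 4), so each list call rests on the preset correlation. Members are counted as called over all genes tested and "adjusted over the list alone". A further 10 lists were written after the results had been seen, with camera adjusted over those 10. Tests of explanations rest on all 4 libraries, and repeats without single libraries, added after the results had been seen, stand beside them. The results for the macrophage list and the female pattern were weaker in such a repeat, and they are given with that limit.

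The named genes are Ube2n with its partners Ube2v1 and Ube2v2, the 12 largest rises and 12 largest falls among called genes with a mean CPM of 1 or more and no overlap between groups (leaving out predicted genes and pseudogenes), up to 4 members with the smallest p in each list, and Sqstm1, Pink1, Zbp1, Ripk3, Mlkl, Gsdmd, Casp8 and Casp1, which the theme of the series names or implies. Any other named gene was chosen after its values were seen, and some genes that the rule picks are not reported here.

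The fit was tested on simulated counts with the means, library sizes and dispersion of these libraries, in which 200 genes were changed. Among 50 genes per size, it recovered 34% of 2-fold, 94% of 4-fold, 100% of 8-fold and 100% of 16-fold changes with 14291 genes tested. It made 24 false calls beside 17, 47, 50 and 50 correct ones at these sizes. The false share of calls in this simulation was thus above the 0.05 of the threshold. With no gene changed it made 2 calls among 14268 genes. Given the recovery of 34%, changes near 2-fold are often missed at this number of libraries. In a further simulation with a raised list, 5 of 200 unchanged lists had a camera p under 0.05. Each gene was drawn independently there, so simulated lists had no correlation between genes, where estimates for the real lists reached 0.62. That rate therefore cannot vouch for list calls at the preset correlation of 0.01. The raised list, with genes 2-fold up, had a camera p of 2.68e-56 at the preset correlation and 0.00489 with an estimated one. Failing to pass with an estimated correlation is therefore weak evidence against a list.

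The alternatives were other scaling (RLE, upper quartile, library size only), other filters on low counts, the DESeq2 1.42.0 Wald test, limma-voom, edgeR's exact test and robust quasi-likelihood, a replicate block, other thresholds, other list tests and leaving out each library in turn. With 1 library left in a group, its spread is assumed to be like that of the other group. Alternatives on the sex of the animals and a crossed pairing were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.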

Results

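Transcripts were counted in 4 mouse liver libraries, 2 from control mice and 2 from mice with a hepatic deletion of Ubc13, at 2 months of age on a normal diet. The series asks how loss of Ubc13 (UBE2N), an enzyme that builds K63-linked ubiquitin chains, bears on fatty liver disease through p62, mitophagy and the combined cell death programme called PANoptosis. Total counts ranged from 16270424 to 17800138 per library. Libraries parted by genotype: Spearman correlations of log2 CPM across genes were 0.974 between the controls and 0.984 between the deletion libraries, against 0.946 to 0.952 across groups. Albumin (Alb) took 10.8% (95% interval 10.83 to 10.86) and 10.3% (10.27 to 10.30) of the counts of control replicates 1 and 2 and 4.87% (4.860 to 4.881) and 4.87% (4.859 to 4.880) of those of deletion replicates 1 and 2.

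The libraries also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome of female cells, had 9 and 2 counts in control replicates 1 and 2 and 9590 and 3896 in deletion replicates 1 and 2. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had between 216 and 1027 counts in each control, 0 counts each in deletion replicate 1 and 206 to 719 counts in deletion replicate 2. For deletion replicate 1, 3 counts allow up to 0.112% of the control level. Relative to the controls, deletion replicate 2 held 0.613 of the Y-linked CPM, and its Xist CPM was 0.38 of that in deletion replicate 1. Every difference between the groups given here therefore runs along with this difference in sex-linked transcripts.

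**Figure D1:**
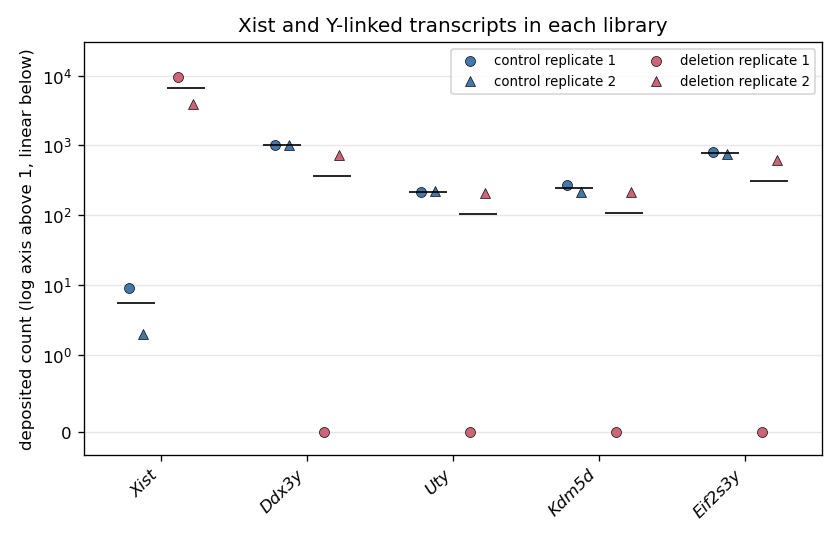
Deposited counts (vertical axis, logarithmic above 1 and linear below) of Xist and 4 Y-linked genes in each library, with bars at group means. Xist has 9 and 2 counts in the controls and 9590 and 3896 in the deletion libraries, and the Y-linked genes have 0 counts in deletion replicate 1 only.

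Ube2n, the targeted gene, fell about 7-fold in the deletion libraries. It had 41.3 and 44.9 CPM in the controls and 5.88 and 5.97 CPM in the deletion libraries, from 669, 654, 107 and 116 counts, a log2 fold change of -2.86 ± 0.16 (edgeR adjusted p = 0.00188, lower in 2 of 2 deletion libraries). The gene (ENSMUSG00000074781) lies on chromosome 10 from 95515145 to 95545657 on the plus strand, and its coding transcript has 4 exons, of which exon 4 (95542272 to 95545657) holds the 3' untranslated region where such libraries read. The labels do not say which exons were flanked, so it is not known whether the counted stretch lies inside the deleted part. Ube2v2, a partner of Ubc13 in K63 chain formation, had a log2 fold change of -0.35 ± 0.25 (adjusted p = 0.453), and Ube2v1, the other partner, had 8, 7, 9 and 5 counts and was below the filter. With the share of male RNA as a covariate, an alternative chosen after seeing the data, the Ube2n log2 fold change was -2.82 with an adjusted p of 0.0643, where the other alternatives gave 1.07e-34 to 0.0121.

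Outside the targeted gene, lists of ductular, inflammatory and interferon-stimulated genes were higher in the deletion livers, and lists of hepatocyte metabolic genes were lower, by a test with a preset correlation. With an estimated correlation 0 of 36 lists passed (lowest adjusted p = 0.264). That setting was weak in simulated data, where a list raised 2-fold had a camera p of 0.00489, against 2.68e-56 at the preset correlation. Failing it does not show that a list was unchanged. The acute phase gene Lcn2 (lipocalin 2) rose from 34.1 ± 8.6 to 1336 ± 144 CPM, the ductular and macrophage gene Spp1 (osteopontin) from 51.4 ± 1.5 to 1621 ± 416 CPM, and the ubiquitin-like modifier Ubd from 0.566 ± 0.365 to 133 ± 21 CPM. The drug-metabolizing enzymes Cyp2c29 and Cyp2c54 fell 7.15-fold and 8.60-fold, and the fatty acid hydroxylase Cyp4a14 fell 11.3-fold. Of 14600 genes tested, 959 were called at an adjusted p under 0.05, 644 higher and 315 lower (67.2% higher), and 764 of these changed at least 2-fold. All 959 had no overlap between groups, as did 56% of all tested genes, where chance gives 33.3% for 2 against 2. With library sizes alone as scaling, 1764 genes were called and 88.5% were higher, and the median of all genes moved by 0.292 on the log2 scale. The count was 1700 without control replicate 1, 2081 without control replicate 2, 499 without deletion replicate 1 and 343 without deletion replicate 2, and 65 with the share of male RNA as a covariate, where 95 of the 114 called genes that the naming rule picked lost their call. That covariate fit had 1 residual degree of freedom less. In it Ube2n stayed at -2.82 and the interferon-stimulated list had a median of 1.41, while the median of NF-kB targets was 0.34. The male share was 0.969 and 1.031 in the controls and 0 and 0.613 in the deletion libraries. The covariate's slope thus came mainly from the 2 deletion libraries, and the values of that fit cannot show what sex contributed. Taking genes on X and Y and the sex-biased lists off the 959 calls, without a new fit, left 924. This does not show how many of the remaining calls follow sex. DESeq2 called 1563 genes, 944 of them in common and all 944 with the same sign.

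**Figure D2:**
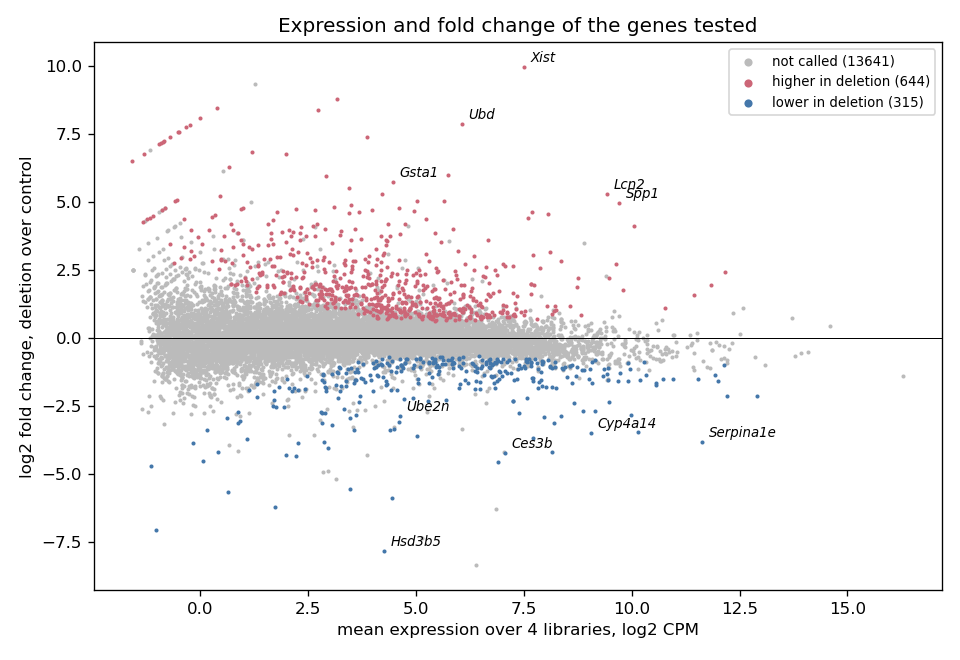
Log2 fold change of deletion over control (vertical axis) against mean log2 CPM over the 4 libraries (horizontal axis) for the 14600 genes tested. The 644 genes called higher are red, the 315 called lower are blue, the others are grey, and Ube2n lies at -2.86.

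The 12 largest rises were in genes with under 2 CPM in each control. After Xist (log2 fold change 9.97 ± 0.76), they included Cdh17, a cadherin of intestine and ductal epithelium, with 1 count over both controls and 680 over the deletion libraries, a ratio of 556 (counting interval 99.5 to 22000). Sprr1a, an epithelial cornified-envelope gene, had 1 and 505 counts, a ratio of 413 (73.8 to 16300). Asb11 and Slc5a9 had 0 control counts and were 27-fold and 20.7-fold higher against 3 counts over the group, with lower counting limits of 21.5 and 16.4. The cholesterol absorption transporter Npc1l1 and Tekt5 had 1 control count each and ratios of 98.1 (17.3 to 3910) and 143 (25.3 to 5680). Without deletion replicate 2, Asb11, Slc5a9, Npc1l1 and Tekt5 lost their calls (adjusted p = 0.0828, 0.127, 0.13 and 0.135). Ubd (log2 fold change 7.89 ± 0.37), the matricellular protein gene Ccn5 (7.42 ± 0.41), Cib3 (6.02 ± 0.25), the transporter Abcc12 (5.97 ± 0.68) and the glutathione transferase Gsta1 (5.73 ± 0.40) completed the set (adjusted p from 0.00188 to 0.00918), and Abcc12 did not pass with limma-voom (0.0513).

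The 12 largest falls were led by Hsd3b5, a male-type steroid dehydrogenase of the liver, which had 14.6 and 61.8 CPM in the controls and 0.0550 and 0.257 CPM in the deletion libraries (log2 fold change -7.84 ± 1.02, adjusted p = 0.0135). The carboxylesterase Ces3b (-4.22 ± 0.28), the bile acid sulfotransferase Sult2a8 (-4.18 ± 0.33), the organic anion transporter Slco1a1 (-4.55 ± 0.82) and Serpina9 (-4.31 ± 0.51) followed. The Mup genes Mup11, Mup9, Mup16 and Mup10 fell by 5.55, 4.34, 3.84 and 3.71 on the log2 scale, and Mup1 had 61 counts over the controls and 3 over the deletion libraries, a ratio of 24.9 (counting interval 8.12 to 124). Values of single Mup genes are uncertain because these copies share reads. Serpina1e and Ces4a, the remaining genes, lost their calls without deletion replicate 2 (adjusted p = 0.0812 and 0.172), as did Mup9 (0.0766) and Mup1 (0.117), and Mup1 and Ces4a also without deletion replicate 1 (0.0635 and 0.0576). Hsd3b5 did not pass with limma-voom (0.121) or robust fitting (0.0504), nor did Slco1a1 with robust fitting (0.123) or Mup16 with a replicate block (0.0695).

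Among genes of the PANoptosis machinery, the necroptosis executor Mlkl rose 7.56-fold (log2 fold change 2.92 ± 0.34, adjusted p = 0.00954) and the nucleic acid sensor Zbp1 rose 5.17-fold (2.37 ± 0.33, adjusted p = 0.016). The pyroptosis executor Gsdmd (1.01 ± 0.18, adjusted p = 0.0319) and the mitochondrial apoptosis effector Bak1 (1.00 ± 0.15, adjusted p = 0.020) rose about 2-fold, and the inflammasome sensor Nlrp6 fell 2.17-fold. Casp8, Casp1 and Ripk3 had log2 fold changes of 0.05 ± 0.17, 0.35 ± 0.33 and 0.61 ± 0.37 (adjusted p = 0.896, 0.577 and 0.371). Of the 31 tested members, 4 rose, 1 fell and 26 did not pass, against 5 and 3 adjusted over the list alone. As a list they had a median log2 fold change of 0.35 (camera adjusted p = 0.0231, or adjusted p = 0.310 with an estimated correlation), and the call was lost without control replicate 1 (adjusted p = 0.0772). Mlkl passed with any 1 library left out. Zbp1 did not without deletion replicate 2 (adjusted p = 0.0523), Nlrp6 did not without deletion replicate 2 (0.115), and Gsdmd and Bak1 did not without deletion replicate 1 (0.0843 and 0.0807) or deletion replicate 2 (0.135 and 0.121). Zbp1 is also an interferon-stimulated gene, and the groups differed in Xist (9 and 2 against 9590 and 3896 counts).

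Of 37 genes of autophagy receptors and mitophagy, 1 passed the test. Sqstm1, the gene of the autophagy receptor p62, had 310 and 296 CPM in the controls and 437 and 509 CPM in the deletion libraries, a log2 fold change of 0.64 ± 0.17 that did not pass (adjusted p = 0.0779). It passed with DESeq2 (adjusted p = 0.0119), with library sizes alone (0.0251) and without a filter on low counts (0.017), and its other alternatives gave 0.0527 to 0.395. The mitophagy kinase Pink1 was at -0.31 ± 0.14 (adjusted p = 0.246). Of the 37 members, 1 fell and 0 rose over all genes and also adjusted over the list alone; at an unadjusted p under 0.05, 1 was higher and 4 were lower, and DESeq2 called 1 higher and 1 lower. The member that fell was the initiation factor Atg13 (-0.91 ± 0.15, adjusted p = 0.0231), and it lost its call without deletion replicate 1 (0.107) or 2 (0.101). The list's median was -0.15 (camera adjusted p = 0.0718), but 0.14 with library sizes alone. In the K63 ubiquitin and TRAF signalling list (30 tested), Tnip1, Birc3 and Traf3, which restrain or relay NF-kB signalling, rose by 1.66, 1.16 and 1.24 on the log2 scale, and 27 members did not pass (5 rose and 0 fell adjusted over the list alone). Birc3 and Traf3 lost their calls without deletion replicate 1 (0.147 and 0.158), Traf3 also without deletion replicate 2 (0.0854). That list's median was 0.07 (camera adjusted p = 0.248, or 0.0342 without deletion replicate 2).

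**Figure D3:**
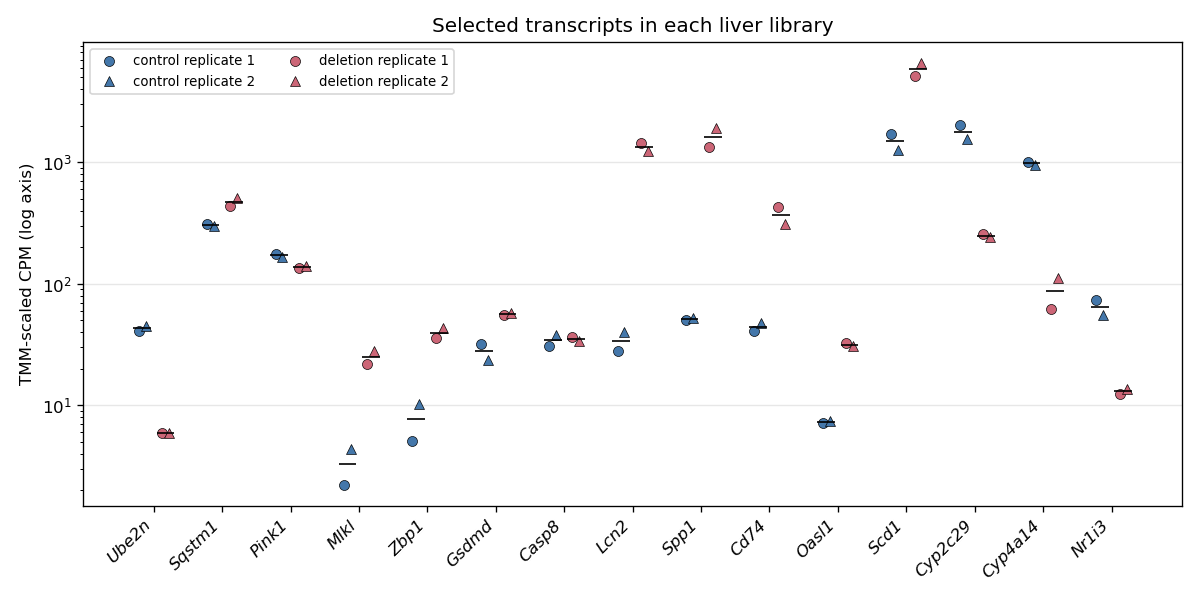
TMM-scaled CPM (vertical axis, logarithmic) of 15 named genes in each library, with controls in blue, deletion libraries in red and bars at group means. Ube2n lies at 41.3 and 44.9 CPM in the controls and 5.88 and 5.97 in the deletion libraries, while Casp8 overlaps between the groups.

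Interferon-stimulated genes were higher as a list in the deletion livers, 1 of 27 lists among 36 that passed (13 up, 14 down; 0 with an estimated correlation, 4 with fry's directional test). Oasl1, an oligoadenylate synthetase-like gene, rose 4.34-fold, the immunoproteasome subunit Psmb9 3.86-fold and the ADP-ribosyltransferase Parp14 3.12-fold (adjusted p from 0.004 to 0.00585). Of the 44 tested members, 24 rose and 0 fell (33 and 0 adjusted over the list alone), and 43 had a positive log2 fold change. No fall was seen at an unadjusted p under 0.05 either (0 members), nor with DESeq2 (0). The median log2 fold change was 1.13 (camera adjusted p = 3.37e-24, or adjusted p = 0.264 with an estimated correlation). Relative to the mean of the controls, the list's median log2 ratio was 0.99 in deletion replicate 1, the library with 9590 Xist counts and 0 Y-linked counts, and 1.21 in deletion replicate 2.

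NF-kB targets and acute phase proteins were higher as well. The chemokine Cxcl16 and the NF-kB subunit Nfkb2 rose 3.68-fold and 5.05-fold, and the interleukin 1 antagonist Il1rn and the adhesion molecule Icam1 3.58-fold and 4.12-fold. Among the 22 NF-kB targets, 7 rose and 0 fell (14 and 0 adjusted over the list alone; 15 and 0 at an unadjusted p under 0.05, 12 and 0 with DESeq2), with a median of 1.19 (camera adjusted p = 7.32e-08, or adjusted p = 0.363 with an estimated correlation). Il1rn lost its call without deletion replicate 1 (adjusted p = 0.0781), Icam1 with a replicate block (0.0775), robust fitting (0.0546) or limma-voom (0.0514). With the share of male RNA as a covariate the NF-kB list had a median of 0.34 and an adjusted p of 0.229, where all alternatives together spanned 1.72e-25 to 0.363. Relative to the mean of the controls, the NF-kB median was 1.34 in deletion replicate 1 and 0.81 in deletion replicate 2. The feedback inhibitor Tnfaip3 had 5.06 and 3.30 CPM in the controls and 59.1 and 13.5 in the deletion libraries, which did not pass (adjusted p = 0.0568), although it did without control replicate 1 (0.00234), control replicate 2 (0.00465) or deletion replicate 2 (0.00475). Of 35 acute phase genes, 8 rose and 1 fell (12 and 2 adjusted over the list alone), led by Lcn2 (log2 fold change 5.29 ± 0.27), Saa2 (4.64 ± 0.44), Orm2 (4.43 ± 0.45) and the endotoxin co-receptor Cd14 (4.38 ± 0.35), all with adjusted p under 0.01, while Saa4, named after its values were seen, fell by 1.66. Their median was 0.56 (camera adjusted p = 4.49e-06, or adjusted p = 0.389 with an estimated correlation), but 0.11 without control replicate 1 and 0.83 without control replicate 2. Of 23 immediate early genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone; 10 and 0 unadjusted, 6 and 0 with DESeq2). These were Klf6 (2.49 ± 0.26), Ier5 (1.88 ± 0.28) and Ier3 (2.06 ± 0.40), of which Ier5 lost its call without deletion replicate 1 (0.0591) and Ier3 without deletion replicate 1 (0.158) or 2 (0.0949). The immediate early list had a median of 0.69 (camera adjusted p = 0.00201, or adjusted p = 0.389 with an estimated correlation; 0.869 with the male RNA covariate, the highest of its alternatives, which started at 1.56e-09). That median was 0.04 with the male RNA covariate, 1.06 without control replicate 2 and 0.40 without deletion replicate 1. Against the controls it was 0.71 in deletion replicate 1 and 0.41 in deletion replicate 2. Xist ran along with each of these lists.

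As lists, markers of monocyte-derived and lipid-associated macrophages and of ductular epithelium were called higher, while those of stellate cells and sinusoidal endothelium were not. Among 29 markers of monocyte-derived and lipid-associated macrophages, 13 rose and 0 fell (21 and 0 adjusted over the list alone; 21 and 0 unadjusted, 15 and 0 with DESeq2). The NADPH oxidase subunit Cybb rose 12.3-fold, the MHC class II chain Cd74 8.38-fold, the protease inhibitor Cstb 4.77-fold and the class II gene H2-Ab1 3.60-fold, and the median was 1.22 (camera adjusted p = 9.67e-19, or adjusted p = 0.264 with an estimated correlation). Of 29 cholangiocyte and ductular reaction genes, 12 rose and 0 fell (15 and 0 adjusted over the list alone; 16 and 2 unadjusted, 13 and 0 with DESeq2). Spp1, the annexin Anxa5, the chaperone Clu and the progenitor transcription factor Sox4 rose by 4.98, 2.59, 2.44 and 2.28 on the log2 scale, and the median was 1.45 (camera adjusted p = 1.72e-12, or adjusted p = 0.342 with an estimated correlation). Several of these genes, such as Spp1 and Clu, are also expressed by other liver cells. The deletion libraries in which these lists rose were also those with 9590 and 3896 Xist counts and with 4.87% of counts from Alb each, where the controls had 10.8% and 10.3%.

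Among 19 Kupffer cell markers, 1 rose and 1 fell (2 and 1 adjusted over the list alone), and the lipoprotein-binding Cd5l was the 1 that rose, by 0.83 on the log2 scale. The Kupffer median was 0.55 (camera adjusted p = 0.0304, or adjusted p = 0.662 with an estimated correlation), a call lost without control replicate 1 (0.371), without deletion replicate 1 (0.216), without the sex-biased genes (0.118) and with the male RNA covariate (0.815, median 0.14). The Kupffer median was 0.33 without control replicate 1 and 0.85 without control replicate 2, and against the controls 0.71 in deletion replicate 1 and 0.40 in deletion replicate 2. Cd5l was lost without control replicate 1 (0.0756), deletion replicate 1 (0.199) or deletion replicate 2 (0.126). Of 7 tested neutrophil genes, Lcn2, which hepatocytes also make, rose and Hdc fell (3 and 1 adjusted over the list alone), with a median of 1.69 (camera adjusted p = 0.00264, or adjusted p = 0.363 with an estimated correlation). The neutrophil list lost its call without control replicate 1 (0.0772; median 1.05, against 2.93 without control replicate 2) and on ranks (0.11), and Hdc without deletion replicate 1 (0.0566). Of 17 T and NK cell genes, edgeR called 0 (0 adjusted over the list alone; 2 at an unadjusted p under 0.05, 1 with DESeq2), with a median of 0.55 (camera adjusted p = 0.174, or 0.0461 without control replicate 2 and 0.0333 on ranks). That median was 0.31 without control replicate 1, 0.91 without control replicate 2, 0.13 without deletion replicate 1 and -0.18 with the male RNA covariate. Of 10 B and plasma cell genes, only Derl3 passed, lower by a log2 fold change of -3.12 (1 adjusted over the list alone), and it was lost without deletion replicate 1 (0.0781) or 2 (0.193) and at -2.00 without control replicate 2; the median was 0.09 (camera adjusted p = 0.867).

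Among 43 stellate cell and matrix genes, Timp1 and Mmp14 rose by 3.60 and 1.13 on the log2 scale and Ecm1 fell by 0.86 (3 and 1 adjusted over the list alone), while the median was -0.08 (camera adjusted p = 0.45, or 0.0269 without control replicate 2) and 0.21 with library sizes alone. All 3 lost their calls without deletion replicate 2 (0.117, 0.139 and 0.221), and Timp1 and Ecm1 also without deletion replicate 1 (0.124 and 0.0754); Timp1 was at 5.56 without control replicate 1. Of 25 sinusoidal endothelial genes, 24 had a negative log2 fold change and the receptor phosphatase Ptprb fell by 0.84 (1 adjusted over the list alone), a call lost without deletion replicate 1 (0.0838) or 2 (0.194). The endothelial median was -0.34 (camera adjusted p = 0.00264, or adjusted p = 0.363 with an estimated correlation), -0.05 with library sizes alone and -0.59 with the male RNA covariate. Of 9 genes of blood and neighbouring tissues, Cela1 fell by 1.27 (1 adjusted over the list alone; lost without deletion replicate 1, 0.0934, or 2, 0.113). Their median was -0.68 (camera adjusted p = 0.00505, or adjusted p = 0.363 with an estimated correlation; 0.0531 without control replicate 1), and it was -0.38 without control replicate 1, -1.11 without control replicate 2, -1.50 without deletion replicate 1 and -2.02 with the male RNA covariate. Haemoglobin transcripts took 0.128% and 0.0643% of counts in the controls and 0.107% and 0.0421% in the deletion libraries, so the groups overlapped.

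**Figure D4:**
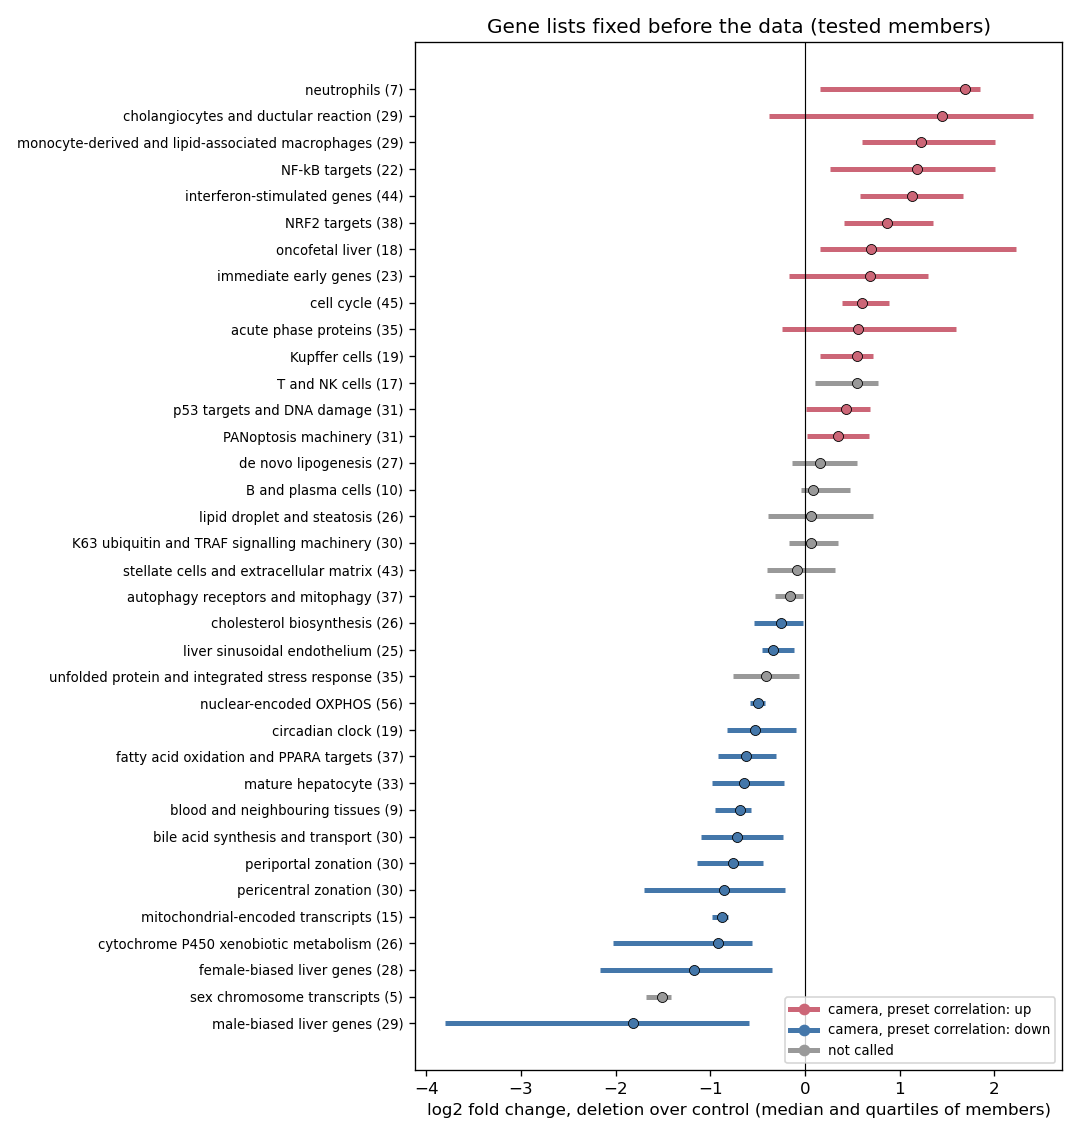
Median (point) and quartiles (bar) of the log2 fold change of deletion over control (horizontal axis) in each of 36 gene lists, with the number of tested members in brackets. Red and blue mark lists called up and down by camera with a preset correlation, of which 0 passed with an estimated correlation; medians run from -1.82 for male-biased genes to 1.69 for neutrophil genes, and these became -0.97 and 2.93 without control replicate 2.

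Genes of the mature hepatocyte were lower as a list. The nuclear receptor Nr1i3 (CAR) fell 4.94-fold, the tryptophan dioxygenase Tdo2 2.91-fold, the transport protein Ttr 3.02-fold and the apolipoprotein Apoa2 2.55-fold. Of 33 such genes, 7 fell and 0 rose (14 and 0 adjusted over the list alone; 18 and 0 unadjusted, 17 and 0 with DESeq2), with a median of -0.65 (camera adjusted p = 1.03e-10, or adjusted p = 0.286 with an estimated correlation). Ttr and Apoa2 lost their calls without deletion replicate 2 (0.0963 and 0.0874), Apoa2 also without deletion replicate 1 (0.0513). Among 26 cytochrome P450 and related genes, 7 fell and 0 rose (19 and 1 adjusted over the list alone; 19 and 1 unadjusted, 16 and 0 with DESeq2). Cyp2c54, Cyp2c29, Cyp2c37 and Cyp2c50, close copies in 1 cluster, fell between 5.11-fold and 8.60-fold, and the list's median was -0.92 (camera adjusted p = 3.69e-14, or adjusted p = 0.264 with an estimated correlation).

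Pericentral and periportal genes were each lower as a list, with some members higher. Of 30 pericentral genes, 9 fell and 3 rose (11 and 3 adjusted over the list alone), with a median of -0.86 (camera adjusted p = 2.26e-09, or adjusted p = 0.312 with an estimated correlation), or -0.52 without control replicate 1. They included Cyp2c54, Cyp2c29, Cyp2c37 and Nr1i3, given above, while, chosen after their values were seen, the transporter Slc1a4 and the glutathione transferase Gstm3 rose 4.37-fold and 17.7-fold. Of 30 periportal genes, 9 fell and 4 rose (18 and 5 adjusted over the list alone), with a median of -0.76 (camera adjusted p = 2.99e-06, or adjusted p = 0.307 with an estimated correlation). The serine dehydratase Sds fell 2.75-fold, the phospholyase Etnppl 5.02-fold and the cortisone reductase Hsd11b1 2.70-fold, while the cadherin Cdh1 rose 3.36-fold; Hsd11b1 lost its call without deletion replicate 2 (adjusted p = 0.0599). Of 30 genes of bile acid synthesis and transport, 7 fell and 3 rose (14 and 5 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 1.05e-05, or adjusted p = 0.307 with an estimated correlation), or -0.45 without control replicate 1. Besides Sult2a8, the bile acid ligase Slc27a5 fell 2.90-fold, the uptake transporter Slc10a1 2.83-fold and the sterol hydroxylase Cyp27a1 2.09-fold. All 3 lost their calls without deletion replicate 2 (0.063, 0.071 and 0.0949), and Cyp27a1 also without deletion replicate 1 (0.0991). Between the groups, Alb, at 10.8% and 10.3% of counts in the controls and 4.87% in each deletion library, and Xist moved with these lists. Against the controls, the pericentral, periportal and bile acid medians were -0.59, -0.61 and -0.56 in deletion replicate 1. They were -1.01, -0.93 and -0.72 in deletion replicate 2, where Xist was lower.

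Fatty acid oxidation genes were lower, and lipogenic genes did not pass as a list. The hydroxylases Cyp4a10, Cyp4a14 and Cyp4a32, targets of the nuclear receptor PPARA, fell 7.26-fold, 11.3-fold and 4.58-fold, while the pantetheinase Vnn1, another PPARA target, rose 3.50-fold. Of 37 members, 7 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 7.89e-11, or adjusted p = 0.264 with an estimated correlation). In de novo lipogenesis (27 tested), the desaturase Scd1 rose 3.90-fold and the phosphatase Lpin1 fell 2.28-fold (1 and 1 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.429). Lpin1 was lost without deletion replicate 1 (0.124) or 2 (0.0591), and the list passed upward without deletion replicate 2 (0.00111) and downward with the male RNA covariate (median -0.35, adjusted p = 0.013). Of 26 lipid droplet and steatosis genes, 3 rose and 2 fell (4 and 3 adjusted over the list alone). The fatty acid transporter Cd36 rose 2.78-fold and the apolipoprotein Apoa4 6.36-fold, the fatty acid binding protein Fabp1 fell 2.83-fold and the lipase Mgll 2.19-fold, and the median was 0.07 (camera adjusted p = 0.595), or 0.43 with the male RNA covariate (0.0813). Mgll lost its call without deletion replicate 2 (0.158). Of 26 cholesterol synthesis genes, Ebp fell by 0.89 on the log2 scale (1 adjusted over the list alone), a call lost without deletion replicate 1 (0.105) or 2 (0.136). That list's median was -0.25, but 0.04 with library sizes alone (camera adjusted p = 0.022, or adjusted p = 0.62 with an estimated correlation). It was lost without control replicate 1 (0.22), without deletion replicate 2 (0.457) and without sex-biased genes (0.0594), and its median was -0.40 without control replicate 2, -0.45 without deletion replicate 1 and -0.07 without deletion replicate 2. With the male RNA covariate it was -0.66 (adjusted p = 3.3e-06, the lowest of its alternatives).

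Respiratory chain transcripts were lower as lists. All 56 nuclear-encoded OXPHOS genes had a negative log2 fold change, 2 fell and 0 rose (39 and 0 adjusted over the list alone; 44 and 0 unadjusted, 13 and 0 with DESeq2), and the median was -0.49 (camera adjusted p = 3.46e-11, or adjusted p = 0.389 with an estimated correlation) or -0.21 with library sizes alone. The 2 were Cox7b (-0.77 ± 0.14) and Uqcrq (-0.80 ± 0.15), both lost without deletion replicate 1 (0.149 and 0.125) or 2 (0.181 and 0.206). Of 15 mitochondrial-encoded transcripts, all had a negative log2 fold change, 4 fell and 0 rose (12 and 0 adjusted over the list alone; 12 and 0 unadjusted, 9 and 0 with DESeq2). These were mt-Atp6 (-1.88 ± 0.25), mt-Co3 (-0.86 ± 0.14), mt-Co2 (-0.88 ± 0.16) and mt-Nd6 (-0.86 ± 0.18), all lost without deletion replicate 2 (0.0643, 0.143, 0.171 and 0.202). Without deletion replicate 1, mt-Co3, mt-Co2 and mt-Nd6 were lost (0.0961, 0.113 and 0.116), as was mt-Nd6 without control replicate 1 (0.0599). The mitochondrial-encoded median was -0.88 (camera adjusted p = 4.74e-09, or adjusted p = 0.264 with an estimated correlation). All genes with mt- symbols together took 5.28% and 5.01% of counts in the controls and 3.86% and 3.92% in the deletion libraries. Mean CPM was 1253 for mt-Nd6, which lies on the minus strand, and 88.6, 42.9 and 97.7 for mt-Atp6, mt-Co3 and mt-Co2 on the plus strand. The strand setting of the counting is not given, so single values of these genes are uncertain. Of 19 circadian clock genes, 2 fell and 0 rose (3 and 0 adjusted over the list alone; 7 and 0 unadjusted, 4 and 0 with DESeq2). The median was -0.53 (camera adjusted p = 0.00821, or adjusted p = 0.307 with an estimated correlation), or -0.32 without control replicate 2 and -0.29 without deletion replicate 2. They were Hlf and Lpin1, and Hlf (-0.81 ± 0.14) was lost without deletion replicate 1 (0.126) or 2 (0.135).

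NRF2 targets, which answer oxidative and electrophilic stress, were higher as a list. Gsta1 rose 53.2-fold, the carbonyl reductase Cbr3 26.1-fold, the sulfiredoxin Srxn1 5.65-fold and the pentose phosphate enzyme Pgd 3.20-fold. Srxn1 lost its call with a replicate block (adjusted p = 0.055). Of 38 members, 10 rose and 0 fell (24 and 0 adjusted over the list alone; 26 and 0 unadjusted, 19 and 0 with DESeq2), with a median of 0.87 (camera adjusted p = 2.18e-12, or adjusted p = 0.31 with an estimated correlation). Among 45 cell cycle genes, 42 had a positive log2 fold change, and Top2a rose 2.15-fold (13 rose and 1 fell adjusted over the list alone). Top2a lost its call without deletion replicate 1 (0.0594) or 2 (0.162), and the list's median was 0.61 (camera adjusted p = 9.91e-06, or adjusted p = 0.264 with an estimated correlation). Of 18 oncofetal liver genes, the trypsin inhibitor Spink1 (log2 fold change 3.58), the desaturase Scd2 (2.44), the Golgi protein Golm1 (3.12) and the glycolytic Aldoa (0.79) rose and 0 fell (7 and 0 adjusted over the list alone; 9 and 0 unadjusted, 6 and 0 with DESeq2). Golm1 lost its call without deletion replicate 2 (0.0874) and Aldoa without deletion replicate 1 (0.102) or 2 (0.195). The oncofetal median was 0.70 (camera adjusted p = 1.19e-05, or adjusted p = 0.342 with an estimated correlation). Of 31 p53 targets, the death receptor Tnfrsf10b rose 4.80-fold (3 rose and 0 fell adjusted over the list alone), a call lost without deletion replicate 1 (0.0602) or 2 (0.0785). The p53 list had a median of 0.44 (camera adjusted p = 0.0172, or adjusted p = 0.389 with an estimated correlation; 0.35 without control replicate 1), or 0.19 without control replicate 1 and 0.28 without deletion replicate 2. Of 35 genes of the unfolded protein and integrated stress response, Aldh18a1 rose 3.52-fold (0 adjusted over the list alone; 3 higher and 5 lower unadjusted, 1 and 2 with DESeq2), a call lost without deletion replicate 1 (0.0754) or 2 (0.227). Their median was -0.41 (camera adjusted p = 0.0551), and the list passed without control replicate 1 (3.06e-08) or deletion replicate 1 (0.03), with library sizes alone (0.0169), without a filter (0.02), at a minimum of 1 CPM (0.0281) and on ranks (0.00645). Between the groups, as for the other lists, these changes ran along with Xist. Between the deletion libraries they did not, since Xist was lower in replicate 2. Against the controls, the NRF2, cell cycle, oncofetal and p53 medians were 0.60, 0.52, 0.50 and 0.27 in deletion replicate 1. They were 0.85, 0.64, 0.82 and 0.47 in replicate 2, and the unfolded protein median went from -0.30 to -0.57.

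Male-biased and female-biased liver genes were each lower as a list. Of 29 male-biased genes, 10 fell and 1 rose (17 and 3 adjusted over the list alone), with a median of -1.82 (camera adjusted p = 7.83e-10, or adjusted p = 0.363 with an estimated correlation), or -0.97 without control replicate 2. The glucuronosyltransferase Ugt2b1 had 662 and 691 CPM in the controls and 152 and 110 CPM in the deletion libraries, and Gstp2, a glutathione transferase picked after its values were seen, was the 1 that rose (10.9-fold). Of 28 female-biased genes, 5 fell and 0 rose (6 and 0 adjusted over the list alone; 13 and 0 unadjusted, 7 and 0 with DESeq2), with a median of -1.17 (camera adjusted p = 2.01e-06, or adjusted p = 0.264 with an estimated correlation), or -0.52 without control replicate 1. Cyp2c40 fell 12.8-fold, the oxidase Hao2 10.1-fold and the prolactin receptor Prlr 2.29-fold. Hao2 and Prlr were lost without deletion replicate 2 (0.0608 and 0.0523), Prlr also without deletion replicate 1 (0.0724), and Cyp2c40 with robust fitting (0.0924). Among 5 sex chromosome transcripts, Xist rose and the 4 Y-linked genes did not pass (1 adjusted over the list alone). That list's median was -1.51 and its mean 0.71 (camera upward, adjusted p = 0.618, or downward with 1.74e-16 without deletion replicate 2, and upward with 0.0492 with a replicate block and 6.06e-21 with the male RNA covariate).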

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

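The alternatives on the sex of the animals and the crossed pairing were chosen after seeing the data. Ube2n stayed between -2.93 and -2.57 on the log2 scale in every alternative and past the threshold in all but the male RNA covariate (-2.82, adjusted p = 0.0643), a fit with 1 residual degree of freedom less. The 959 calls became 928 to 998 with RLE or upper-quartile scaling, other CPM minimums or robust fitting, 914 with limma-voom and 764 with a 2-fold minimum. They became 1764 with library sizes alone (843 shared), 2768 without a filter, 1563 with DESeq2, 1855 with the exact test, 191 at 0.01, 1862 at 0.1 and 65 with the male RNA covariate (63 shared), and 343 to 2081 when 1 library was left out. For the last, 300 to 933 were shared. Lists called went from 27 to 0 with an estimated correlation, 4 with fry, 22 to 29 when 1 library was left out and 23 to 29 otherwise. Without 1 control the calls rose, because the spread then came from the deletion pair alone, the closer pair (Spearman 0.984 against 0.974 for the controls). A call kept without a control is therefore a weak check. Apart from this and the effect of fewer libraries or degrees of freedom, the cause of these changes was not tested.

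The replicate numbers did not pair the libraries: across genes, the difference between the controls and that between the deletion libraries had r = -0.12 (Spearman -0.167). With a replicate block, 390 genes were called (370 shared), Ube2n was at -2.86 (adjusted p = 0.0121) and 28 lists passed. The block ended 37 of the 114 calls on named genes, among them Mup16, Icam1 and Srxn1, which passed with any 1 library left out, and a crossed pairing gave 1366 calls.

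The PANoptosis list (median 0.348) lost its call with an estimated correlation (adjusted p = 0.31), with fry (0.0731) and without control replicate 1 (median 0.429; 0.328 to 0.477 when 1 library was left out), and the autophagy list passed without a filter (-0.14, adjusted p = 0.0367) and on ranks (-0.15, 0.0203). Reversals (for lists, of the camera direction, given here with medians) were in results that had not passed. With library sizes alone they were the B and plasma (0.37) and sex chromosome lists (-1.18), and the last also without a filter (-1.59), on ranks (-1.51) and without deletion replicate 2 (-11.01). Leaving out 1 library reversed Casp8 (-0.099 to 0.206) and the stellate (-0.27 to 0.122), B and plasma (-0.073 to 0.632), lipid droplet (0.007 to 0.324), unfolded protein (-0.583 to 0.072), sex chromosome (-11.01 to -0.524) and lipogenesis (-0.093 to 0.436) lists in at least 1 setting each. The male RNA covariate reversed Cd22 (-0.10), Ddx3y (5.10), Eif2s3y (5.08), Kdm5d (4.54), Casp8 (-0.04), and the B and plasma (-0.15) and lipogenesis (-0.35, camera adjusted p = 0.013) lists. Y-linked CPM was lower in both deletion libraries than in the controls, so that fit overcorrected these genes for sex and cannot weigh it. For the other reversals the cause was not tested. Depth limits genes under 0.169 to 0.184 CPM, where 3 counts are expected, and about 2-fold changes were often missed in simulated data.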

Other observations

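Gene groups outside the fixed lists were collected after the results had been seen, so their counts describe these libraries and are not independent evidence; with library sizes alone as scaling, the median of all genes moves by 0.292. Antigen presentation by MHC class I was higher in the deletion livers: of 18 tested genes, all had a positive log2 fold change and 9 rose, among them the peptide transporter Tap1 (1.47), the class I gene H2-Q4 (1.45) and the regulator Nlrc5 (1.28). Their median was 1.01 (camera adjusted p = 4.82e-13, or adjusted p = 0.191 with an estimated correlation). Of 27 genes of the actin, tubulin and annexin cytoskeleton, 11 rose and 0 fell (19 and 0 at an unadjusted p under 0.05, 16 and 0 with DESeq2). S100a11 rose by 3.08, Anxa2 by 2.73, Lgals1 by 2.32 and Tubb2b by 3.37 on the log2 scale, and the median was 0.85 (camera adjusted p = 4e-11, or adjusted p = 0.168 with an estimated correlation). Of 11 TNF receptor family genes, Tnfrsf12a (2.53), the receptor of the cytokine TWEAK, and Tnfrsf10b (2.26) rose, with a median of 0.70 (camera adjusted p = 0.000527, or adjusted p = 0.191 with an estimated correlation). Of 39 lysosomal and TFEB target genes, 4 rose, led by the GTPase Rragd (5.07), with a median of 0.19 (camera adjusted p = 0.0106, or adjusted p = 0.191 with an estimated correlation; 0.0518 without control replicate 2) and 0.12 without deletion replicate 2.

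Secreted hepatocyte products were lower in part. Of 20 Mup genes, 11 fell and 0 rose (15 and 1 unadjusted, 14 and 1 with DESeq2), with a median of -3.31 (camera adjusted p = 2.58e-16, or adjusted p = 0.191 with an estimated correlation), while Mup20 was at 2.29 (adjusted p = 0.0612). Of 20 coagulation genes, F11 fell 2.37-fold and the median was -0.33, or -0.03 with library sizes alone (camera adjusted p = 0.00141, or adjusted p = 0.205 with an estimated correlation). Of 19 complement genes, C8g and Mbl2 fell by 1.57 and 1.03, and the median was 0.23 but the mean -0.02 (camera downward, adjusted p = 0.706); the median was 0.06 without control replicate 1, 0.37 without control replicate 2 and 0.08 without deletion replicate 1. Cytosolic ribosomal protein genes (79 tested) had 0 calls (0 higher and 28 lower unadjusted, 0 and 3 with DESeq2) and a median of -0.34, or -0.05 with library sizes alone (camera adjusted p = 3.93e-07, or adjusted p = 0.559 with an estimated correlation). Of 20 YAP and TEAD targets, 2 rose and 1 fell (median -0.03, or 0.26 with library sizes alone; camera adjusted p = 0.969). Of 5 growth hormone and STAT5 targets, edgeR called 0 (1 higher and 3 lower both at an unadjusted p under 0.05 and with DESeq2; camera adjusted p = 0.116, or 0.00512 without control replicate 1 and 0.0438 without deletion replicate 1). The controls also differed from each other in sex-dependent genes: Sult2a1 had 313 and 6.66 CPM, Cyp7b1 9.75 and 118 CPM and Mup7 5.06 and 330 CPM in control replicates 1 and 2.

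In the patterns that follow, the tests of a female pattern, of hepatocyte share and of both explanations for the sex-linked transcripts were chosen after the values they use had been seen, as were the repeats without 1 library, and the tests of the sex of the animals and of growth hormone were written first. Deletion replicate 2 holds Xist and Y-linked transcripts together. A single animal with 2 X chromosomes and a Y would keep the Y-linked genes at the control level, but their mean ratio was 0.656 ± 0.042 (SE over 4 genes), which argues against it. The Y-linked share and the Xist share add up to 0.994, as RNA of male and female livers in 1 library would give, for instance from a pool of mice or carry-over. Carry-over from the 2 controls at that share would move Ube2n and Alb in deletion replicate 2 well toward the control level. Ube2n was instead at 5.97 CPM there and 5.88 CPM in replicate 1, and Alb took 4.87% of counts in both. This argues against the controls as the source. A pool and carry-over from other samples are not separated by these data. A mislabelled sample would not by itself give both kinds of transcript in 1 library.

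Interferon-stimulated, macrophage and ductular genes were higher in the deletion libraries. If the sex of the animals were the whole cause, deletion replicate 2 would show the change of replicate 1 diluted to its Xist share. Its median log2 ratio lay above that by 0.75 ± 0.13 (bootstrap SE) for interferon-stimulated genes, 0.50 ± 0.18 for the macrophage list and 1.08 ± 0.33 for the ductular list. If the Xist share measures female RNA, these lists changed more in deletion replicate 2 than dilution alone would give. The SE is over genes and not over animals, with 1 library on each side, so this cannot decide whether sex was the whole cause. Without control replicate 1 the 3 differences were 0.84 ± 0.06, 0.41 ± 0.22 and 1.19 ± 0.28, the macrophage one within 2 SE of 0. Without control replicate 2 they were 0.78 ± 0.18, 0.53 ± 0.18 and 0.86 ± 0.33. A lower share of hepatocytes as the whole cause would raise every other cell type alike. The endothelial median lay below that of the macrophage list by a log2 difference of -1.56 ± 0.31 (-1.40 ± 0.45 without control replicate 1). This argues against it for the macrophage list, and the ductular and interferon-stimulated lists were not compared in this way. The sex of the animals, a lower share of hepatocytes for those lists or in part, and a response to the deletion stay open. So do a change in particular cell types and an unlabelled difference between the animals, such as litter or housing.

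Male-biased liver genes were lower in the deletion libraries. A female pattern of liver expression would raise the female-biased list. That list's median log2 fold change was instead -1.17 ± 0.34 (SE over genes), at -1.28 and -1.07 in deletion replicates 1 and 2. This argues against a female pattern on its own, more weakly without control replicate 1, at -0.52 ± 0.34, still negative but within 2 SE of 0. With the male RNA covariate the female-biased median was -0.90 (camera adjusted p = 0.00835), where camera with an estimated correlation and no covariate gave 0.264. In deletion replicate 2 the male-biased median log2 ratio to the controls was -1.49 ± 0.48 (-1.37 in replicate 1). This lay below the -0.71 that its Y-linked share would give but within 2 SE. It was -2.20 ± 0.50 and -0.89 ± 0.58 without control replicates 1 and 2. Sex as the whole cause therefore cannot be told apart from the genotype here. The list passed with the male RNA covariate (median -1.69, camera adjusted p = 1.63e-06), where camera with an estimated correlation and no covariate gave 0.363. That fit put the Y-linked Ddx3y, Eif2s3y and Kdm5d at 5.10, 5.08 and 4.54, although their CPM was lower in both deletion libraries than in the controls. Its values for the male-biased and female-biased lists therefore weigh neither for nor against sex. Lower growth hormone and STAT5 output may contribute: the median of Igf1, Igfals, Socs2, Cish and Ghr was -0.76 ± 0.61 (-0.41 without control replicate 2), which leaves it open as well.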
